A study of Arabidopsis thaliana with 2 samples.

How the data were processed

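Transcripts of Arabidopsis Col-0 roots were measured on a pair of 2-colour Agilent arrays, each carrying an aluminium and a control sample, with 1 µg of total RNA labelled per sample per the labels' protocols. The seedlings grew for 10 days at pH 5.5 in 2% MGRL nutrient solution with 200 µM CaCl2, at 23 °C with 12 h of light per day at 30 µmol m-2 s-1, before the 6 h treatment at pH 5.0. The labels call the arrays biological replicates 1 and 2. Dye orientation, array layout, scanner software version and replicate change together, so none of them can be told apart from the others.

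The deposited scanner files give spot intensity values per channel, not normalized, per the file headers made with Feature Extraction 8.1.1.1 for replicate 1 and 7.1.1 for replicate 2, whereas the submitters' processing notes name version 9.5.1.1. The deposited intensity values of replicate 2 hold 3 significant digits. The same files hold the scanner software's log10 ratio of Cy5 over Cy3, computed from its own background-corrected and dye-normalized signals per the file headers. The series matrix deposited by the authors holds log2 values for 20346 probes. Set against the scanner ratios, its columns were on the log2 scale in the direction of aluminium over control (r = 0.998 for replicate 1 and 0.887 for replicate 2), with medians of -0.0103 and -0.0112. The normalization and centring behind them stay unknown.

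Mean signals were corrected with normexp (offset 50) against the median local background and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots (736 and 1075) at weight 0. The ratio of replicate 1 was turned so that both arrays give aluminium over control. Of 21500 probes, 108 had an outlier mark on either array and 1151 others were not well above background in at least 1 channel on each array. A further 1047 kept probes had no locus shared by both array layouts and were left out of the gene test. In all, 1063 probes had no locus in the newer layout and 158 had different loci in the newer and older layouts. The 19194 genes left had 1 probe each, so that the rule for several probes (the brightest) changed nothing. Of these, 19118 were found in the RefSeq gene table of assembly TAIR10.1, which was used for symbols only, and 8830 had a symbol other than the locus. Gene names are those of the array's design. The files name no genome build, so no coordinates are given. A value that is below background in all arrays of a treatment would be given as a bound, which no gene named here needed. The spot of UBQ10 was saturated in the aluminium channel of both arrays, and no fold is given for it.

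Genes were tested with lmFit and eBayes on both ratios against 0, two-sided, with 1 residual degree of freedom and a prior of 4.06, and Benjamini-Hochberg adjustment. A dye term would leave no residual degrees of freedom. With 2 arrays an exact sign-flip test cannot go under p = 0.5, so the test borrows its spread from all genes. Before the data were examined, 28 gene lists with 617 loci were fixed (572 tested), and the 27 lists with at least 5 tested genes were tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Of the 13 lists called, none was called with an estimated correlation, which rests on 1 residual degree of freedom, and none by fry, whose directional test asks whether the genes of a list move on balance one way. Named genes follow a rule fixed at the same time, over genes with a symbol: the 12 higher and 12 lower with the largest smaller-of-2 ratio among those past adjusted p 0.05 and changed the same way on both arrays, every measured member of the aluminium tolerance list, and up to 4 members with the smallest p in each other list. Outside this rule, SCR and MYB36 were named in tests written before their values were seen, and PR1, PR2, PR5, SGN3 and CASP5 were chosen after their values were seen, as were the genes so marked in the closing part. The values of 1 gene that the rule takes are not reported here.

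The procedure was tested on simulated data: in 20 runs over 19194 genes, 200 genes were changed in data drawn from the fitted spread. Of genes changed by 0.5 on the log2 scale 2.60% were recovered, of those changed by 1 86.9%, by 2 99.8% and by 3 99.9%. Of the genes called, 9.01% on average were unchanged (range 4.14 to 14.5%, nominal 5%), and the prior was fitted at 4.77 degrees of freedom on average where 4.06 had been simulated. The 200 changed genes were far fewer than the 1583 higher and 1243 lower genes called in the data. The cutoff was therefore stricter in the simulation, and its recovery of small changes and its false share need not hold for the data. Of 200 sets of 20 unchanged genes, camera put 1.68% under p 0.05. The simulated genes were drawn independently, whereas camera assumed a correlation of 0.01, which favours a low rate. It does not show how camera fares on lists of correlated genes. Alternatives covered background correction, the normexp offset, loess against median centring, separate channels, the filter on dim probes, several probes, the series matrix values, the variance model, the threshold, an unmoderated test, the set test, gene naming and each replicate alone.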

Results

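Roots of 10-day-old Arabidopsis thaliana seedlings of the Col-0 accession, grown in hydroponics, were exposed for 6 h to 10 µM AlCl3 at pH 5.0 or to the same pH without AlCl3. Aluminium ions released at low pH are toxic to root tips. Total root RNA from both treatments was labelled with different dyes and hybridised together on a 2-colour Agilent array, so that each array gives a ratio of aluminium over control for every probe. There were 2 biological replicates with opposite dye orientation: the aluminium RNA carried Cy3 on replicate 1 and Cy5 on replicate 2. The median signal was between 4.60 and 8.62 times the local background over the 4 channels, and between 94.4% and 96.4% of the 21500 probes were well above background in each channel. The 2 arrays are the limit on precision. All values below are log2 ratios of aluminium over control, with the SD over the 2 arrays (n = 2), and adjusted p-values come from limma with Benjamini-Hochberg adjustment over 19194 genes.

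The comparison asks which transcripts differ between aluminium-treated and control roots. Among gene lists fixed before the data were examined, those of defence, WRKY and calcium signalling, ethylene and aluminium tolerance were higher in the aluminium RNA, and those of the endodermis, cell division, iron deficiency and nitrogen were lower by camera's test. None of these list calls held with an estimated correlation (adjusted p = 0.841, and adjusted p = 0.934 for nitrogen). The genes named next were ranked among those with a symbol, and some genes without one, given in the closing part, changed as much or more. The ubiquitin ligase gene PUB54 (AT1G01680) had a log2 ratio of 4.41 ± 0.36, which is 21.2-fold (adjusted p = 0.00123). By the smaller of the 2 ratios, the ATPase gene AATP1 followed at 3.92 ± 0.092. After it came PBS3, whose product acts in salicylic acid biosynthesis, at 3.39 ± 0.32. On the other side, ESB1 (AT2G28670), a dirigent protein gene needed for the lignin of the Casparian strip, had a log2 ratio of -3.11 ± 0.16, or 8.62-fold lower (adjusted p = 0.00123), and the BTB-domain gene BT1 had -3.26 ± 0.47. In all, 1583 genes were higher and 1243 lower in the aluminium RNA at an adjusted p under 0.05. Of all genes tested, 314 were at least 2-fold higher and 171 at least 2-fold lower on both arrays, while 1 gene was 2-fold on both with opposite signs, as a dye effect would leave it. When the ratios were turned by dye instead of by treatment, limma called 0 genes and had 20 at an unadjusted p under 0.05, fewer than chance gives, since the treatment difference then enters the residual spread and leaves that fit little power to find a dye effect. Across genes, which are not independent replicates, the ratios of the 2 arrays had a Pearson r of 0.80 and a Spearman rho of 0.66.

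The count of calls changed with the processing of the ratios, and 15 of the 115 called named genes had ratios over 1.5 times as far from 0 with the series matrix values. The scanner software's own ratios gave 170 higher and 118 lower genes, and the series matrix values gave 0 in limma, with 5073 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0535. In data simulated from the fitted spread, 9.01% of the genes called were false on average, against the nominal 5%. Only 200 genes were changed there, far fewer than were called in the data, so the share may differ in the data.

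**Figure D1:**
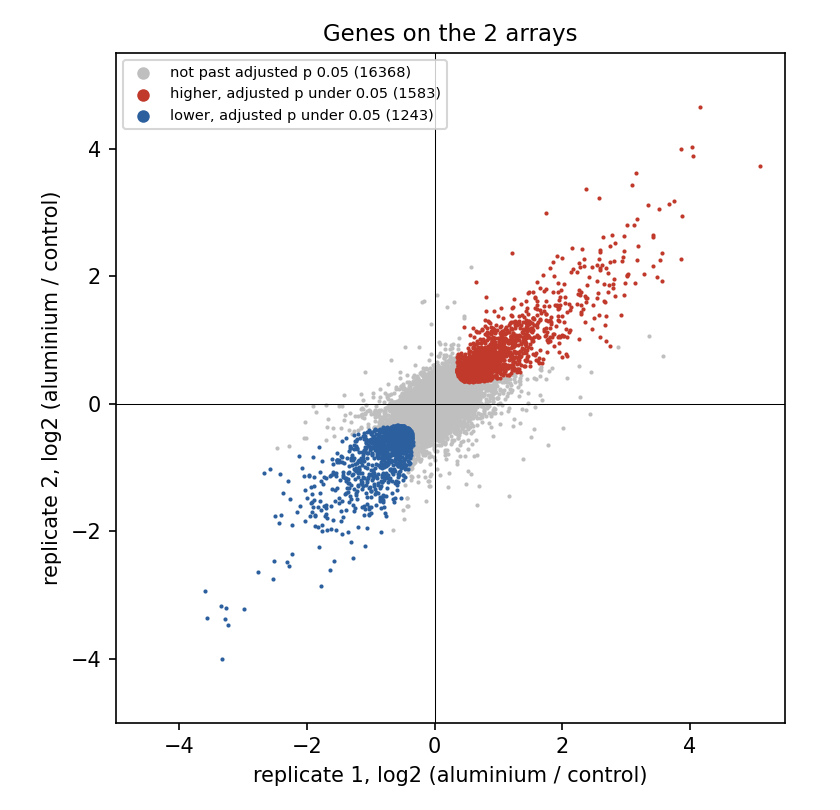
Each point is 1 of 19194 genes, with its log2 ratio of aluminium over control on replicate 1 (horizontal) and replicate 2 (vertical); red and blue points are the 1583 higher and 1243 lower genes at an adjusted p under 0.05, and grey points are the rest. The coloured genes lie along the diagonal, as selection by a test on both arrays favours.

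The other higher genes named by size were the membrane protein gene NHL3 (3.41 ± 0.39), the beta-glucosidase gene BGLU25 (3.23 ± 0.16), the germin-like gene GLP6 (3.28 ± 0.33), the transcription factor genes WRKY50 (2.80 ± 0.24), ZAT7 (2.61 ± 0.20) and HB53 (2.60 and 2.41 on the 2 arrays), the arabinogalactan protein gene AGP2 (2.63 ± 0.018), the calmodulin-like gene CML41 (3.02 ± 0.58) and cwINV6 (2.83 ± 0.51), a member of the glycosyl hydrolase family of cell wall invertases. GLP6 has close copies among the germin-like genes, and its probe may not separate them. The other lower genes were the nicotianamine synthase gene NAS4 (-2.64 ± 0.15), the peroxidase gene PER64 (-2.40 ± 0.12), the transcription factor genes HRS1 (-2.42 ± 0.18), BHLH100 (-2.15 ± 0.39) and BHLH38 (-1.94 ± 0.14), the outward potassium channel gene SKOR (-2.30 ± 0.093), the carbonic anhydrase gene CA2 (-1.88 ± 0.076), the tonoplast aquaporin gene DELTA-TIP (-2.32 ± 0.76), the aspartate kinase gene CARAB-AK-LYS (-1.83 ± 0.10) and the fasciclin-like gene FLA9 (-1.86 ± 0.14). All 24 had an adjusted p under 0.05, the highest being 0.00891 for DELTA-TIP.

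**Figure D2:**
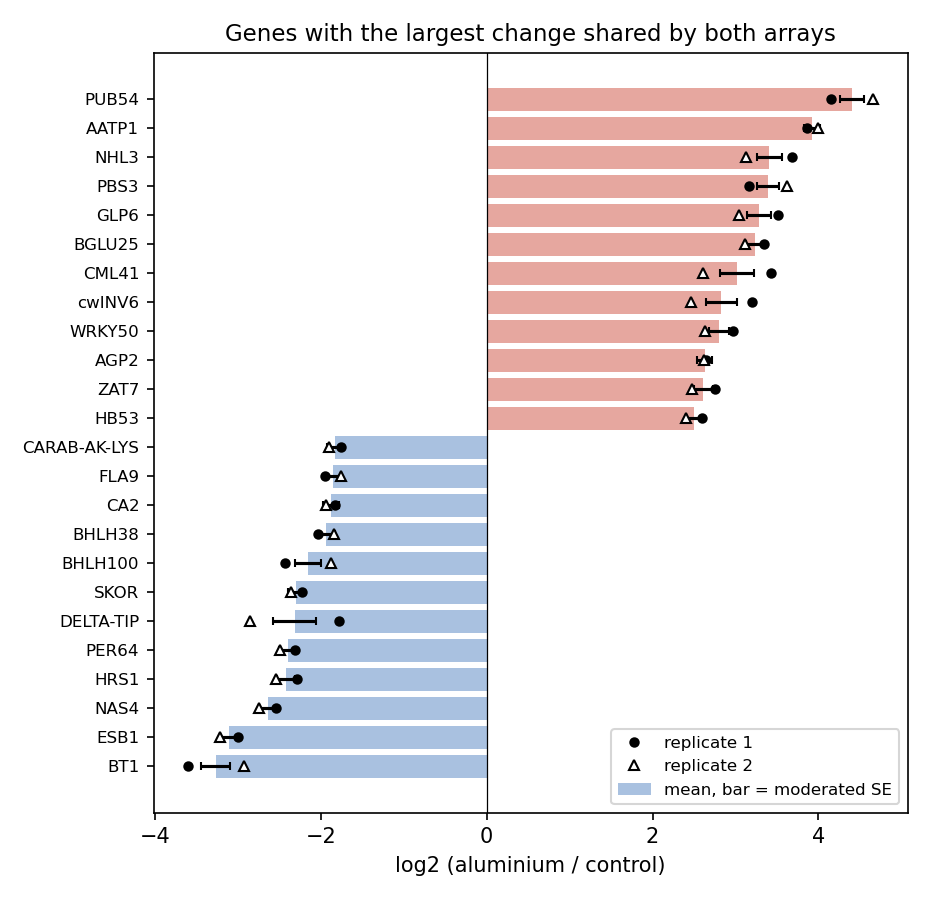
Bars give the mean log2 ratio of aluminium over control for the 12 higher and 12 lower named genes with the largest change shared by both arrays, error bars the moderated SE, filled circles replicate 1 and open triangles replicate 2. Both arrays lie on the same side of 0 for every gene shown, from -3.26 for BT1 to 4.41 for PUB54.

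Of the 20 genes listed before the data were examined as known from aluminium tolerance, 8 rose, 0 fell and 12 did not pass, and adjusted over the list alone 11 were higher and 1 lower. ALMT1 (AT1G08430), the malate transporter that releases malate from the root, had 1.94 ± 0.084, or 3.84-fold (adjusted p = 0.00206). The ABC transporter genes ALS1 and ALS3, both required for tolerance, had 0.89 ± 0.27 and 0.83 ± 0.14. RAE1 and RAH1, F-box genes that act on the transcription factor STOP1, had 0.89 ± 0.13 and 0.54 ± 0.082. GDH1 rose by 1.12 ± 0.16, CAMTA2 by 0.78 ± 0.21, and PGIP1 by 1.42, with 2.06 on replicate 1 and 0.78 on replicate 2. The citrate transporter gene MATE had 0.13 ± 0.016 and STOP1 itself 0.33 ± 0.17, neither past the threshold. WRKY46, a repressor of ALMT1, had 0.57 and 2.14 on the 2 arrays (adjusted p = 0.0716). Other members that did not pass were GDH2 (1.67 and 0.54 on the 2 arrays), CIPK23 (-0.37 ± 0.13), NIP1;2 (-0.20 ± 0.033) and WAK1 (0.12 ± 0.11). The remaining members did not pass either and were of opposite sign on replicates 1 and 2, namely PGIP2 (0.57 and -0.13), STAR1 (0.03 and -0.23), TDT (-0.14 and 0.02), HSFA2 (0.12 and -0.26) and STOP2 (0.12 and -0.19). Camera gave the list an adjusted p = 0.00125, against an adjusted p = 0.841 with an estimated correlation, and the list median was 0.57 on replicate 1 and 0.34 on replicate 2.

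Of 11 defence genes tested, 7 rose, both over all genes and adjusted over the list alone, and 4 did not pass. The members with the smallest p were SID2 (2.30 ± 0.21), which encodes isochorismate synthase for salicylic acid, NHL10 (1.74 ± 0.11), PAD4 (2.12 and 1.47 on the 2 arrays) and the MYB factor gene MYB51 (1.39 ± 0.13). The pathogenesis-related genes PR1 (-0.01 ± 0.11), PR2 (0.16 ± 0.13) and PR5 (0.03 ± 0.28) did not pass. The list median was 1.095 on replicate 1 and 0.83 on replicate 2 (camera adjusted p = 6.56e-05, and adjusted p = 0.841 with an estimated correlation). In the list of WRKY and calcium signalling genes 12 of 32 rose and 2 fell, or 15 and 2 adjusted over the list alone, among them WRKY51 (2.31 ± 0.23), WRKY6 (1.28 ± 0.010), WRKY33 (1.19 ± 0.017) and WRKY75 (1.17 ± 0.083). With list medians of 0.53 and 0.46 on replicates 1 and 2, camera's adjusted p = 6.15e-06, and adjusted p = 0.841 with an estimated correlation. The list call does not extend to broader families formed from probe descriptions after the data had been seen. Of 62 genes described as WRKY factors 14 rose and 6 fell, and camera did not call them (adjusted p = 0.103). Nor did it call the calcium-binding EF hand (adjusted p = 0.199), calcium-dependent protein kinase (adjusted p = 0.140) and calmodulin-related (adjusted p = 0.103) families.

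Among hormone lists, 11 of 25 ethylene genes rose and 0 fell, with ERF2 at 1.01 ± 0.030, ERF1A at 0.87 ± 0.11 and the ACC synthase gene ACS6 at 0.93 ± 0.14. Adjusted over the list alone 13 were higher and 1 lower. By camera the adjusted p = 8.01e-05 for this list, and the adjusted p = 0.841 with an estimated correlation, with medians of 0.46 on replicate 1 and 0.36 on replicate 2. For abscisic acid 7 of 20 rose by either adjustment, including LEA7 (1.06 ± 0.15), ABI1 (0.96 ± 0.30) and CYP707A1 (1.45 ± 0.45), whose enzyme breaks the hormone down. Camera gave the list an adjusted p = 0.0173, against an adjusted p = 0.841 with an estimated correlation, and the list median was 0.19 on replicate 1 and 0.12 on replicate 2. The auxin list was not called (adjusted p = 0.324), with 3 genes higher, such as GH3.2 (0.90 ± 0.16), and 7 lower, such as IAA14 (-0.68 ± 0.10), or 6 and 9 adjusted over the list alone. Nor was the jasmonate list (adjusted p = 0.842), with 1 gene higher, CYP94C1 (1.33 ± 0.26), and 1 lower, AOC4 (-0.59 ± 0.090), the same counts being found adjusted over the list alone.

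Of the genes that passed in the 2 detoxification lists, more rose than fell. In the glutathione transferase list 13 of 39 rose and 3 fell, or 14 and 4 adjusted over the list alone. GSTU8 had 2.36 ± 0.32, GSTU22 2.21 ± 0.091 and GSTF2 1.73 ± 0.28, while GSTU28 had -1.92 ± 0.32. The list median was 0.58 on replicate 1 and 0.17 on replicate 2 (camera adjusted p = 0.00125, and adjusted p = 0.841 with an estimated correlation). In the xenobiotic list 7 of 17 rose and 2 fell, or 8 and 2 adjusted over the list alone, with CYP81D8 at 1.26 ± 0.30, ABCC3 at 0.81 ± 0.25 and the glycosyltransferase gene UGT74E2 at -1.57 ± 0.15. With list medians of 0.85 and 0.25 on replicates 1 and 2, camera's adjusted p = 0.00801, and adjusted p = 0.841 with an estimated correlation. The endoplasmic reticulum stress list had 2 of 18 higher and 1 lower, or 7 and 1 adjusted over the list alone. BZIP60, a transcription factor of the unfolded protein response, had 1.36 ± 0.12 and the chaperone gene BIP3 1.33 and 1.07 on the 2 arrays, the latter gene above background in the control channel of 1 array only. By camera the adjusted p = 0.0173 for this list, and the adjusted p = 0.841 with an estimated correlation, with medians of 0.36 on replicate 1 and 0.16 on replicate 2, and the call ended with median centring.

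The endodermis is the cell layer that carries the Casparian strip. Of 8 endodermis markers 4 fell by either adjustment and 4 did not pass. Besides ESB1 and PER64, the scaffold gene CASP1 had -1.74 ± 0.081. The identity gene SCR had -0.27 ± 0.20, the regulator MYB36 -0.23 ± 0.19, the receptor kinase gene SGN3 -0.12 ± 0.10 and CASP5 -0.01 ± 0.012, none past the threshold. Camera gave the list an adjusted p = 8.01e-05, against an adjusted p = 0.841 with an estimated correlation, and the list median was -0.66 on replicate 1 and -0.59 on replicate 2. Of 17 root hair markers 5 fell, among them EXPA7 (-1.73 ± 0.14) and the transcription factor genes RSL4 (-1.47 ± 0.19) and RHD6 (-0.67 ± 0.14), and the list was not called (adjusted p = 0.221), although it was called lower with median centring. Adjusted over the list alone 1 was higher and 6 lower. The root cap list held 3 measured genes, too few for the list test, with 2 lower adjusted over the list alone and 0 over all genes. No green shoot marker passed by either adjustment (limma called 0 of 20, with 1 at an unadjusted p under 0.05), and the list median was 0.20 on replicate 1 and -0.12 on replicate 2.

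All 18 members of the cell division list had a negative ratio on both arrays, 4 passed over all genes and 12 adjusted over the list alone. They included KNOLLE (-0.62 ± 0.25), needed for cytokinesis, the mitotic genes CDC20.1 (-0.93 and -0.42 on the 2 arrays) and CYCB1;1 (-0.46 ± 0.00744) and the stem cell regulator PLT1 (-0.47 ± 0.073). The list median was -0.50 on replicate 1 and -0.24 on replicate 2 (camera adjusted p = 6.15e-06, and adjusted p = 0.841 with an estimated correlation). Of the cell wall loosening expansins 5 of 20 fell and 0 rose, or 6 adjusted over the list alone, such as EXPA14 (-1.62 ± 0.45) and EXPA18 (-1.08 ± 0.32). With list medians of -0.06 and -0.27 on replicates 1 and 2, camera's adjusted p = 0.0288, and adjusted p = 0.841 with an estimated correlation, and the call ended with the scanner software's ratios and with the series matrix values. A family of 24 genes described as expansins, formed after the data had been seen, had 0 higher, 4 lower and a median of -0.01. Camera did not call it (adjusted p = 0.386). Xyloglucan endotransglucosylase genes went both ways, 6 higher and 7 lower of 33, with XTH18 at 1.98 ± 0.55 and XTH8 at -1.74 ± 0.37. The list was not called, except as higher with median centring (adjusted p = 0.337 in the main setting), and adjusted over the list alone 10 were higher and 7 lower.

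Of the iron acquisition genes that passed, more fell than rose. Of 22 genes of the iron deficiency list 9 fell and 2 rose, or 10 and 2 adjusted over the list alone. The iron transporter gene IRT1 had -1.61 ± 0.021, or 3.06-fold lower (adjusted p = 0.00265), and BHLH39, a transcription factor gene induced by iron deficiency, -1.81 ± 0.084. By camera the adjusted p = 7.00e-04 for this list, and the adjusted p = 0.841 with an estimated correlation, with medians of -0.25 on replicate 1 and -0.31 on replicate 2. The nitrogen list had 8 lower and 5 higher of 24, or 12 and 5 adjusted over the list alone. HRS1 and LBD37 (-1.35 ± 0.20), transcription factor genes of the nitrate response, and the glutamate synthase gene GLT1 (-1.21 ± 0.12) fell, while the ammonium transporter gene AMT2 rose by 1.83 ± 0.21. Camera gave the list an adjusted p = 0.0148, against an adjusted p = 0.934 with an estimated correlation, and the list median was -0.17 on replicate 1 and -1.04 on replicate 2. With median centring those medians were -0.55 and -0.75. The call ended with the scanner software's ratios and with the series matrix values.

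The remaining lists were not called. Organic acid metabolism (adjusted p = 0.353) had 5 higher genes, among them the malic enzyme gene NADP-ME2 (1.14 ± 0.42), and 6 higher with 4 lower adjusted over the list alone. In the reactive oxygen list (adjusted p = 0.842) 4 rose, such as ZAT12 (1.62 ± 0.051), and 3 fell, such as the superoxide dismutase gene FSD1 (-0.67 ± 0.016), with 5 and 6 adjusted over the list alone. That list's median was 0.00, with 0.04 on replicate 1 and -0.05 on replicate 2, while its mean was 0.02 and its camera direction was down. The phenylpropanoid list (adjusted p = 0.313) had 3 higher and 3 lower genes, F5H being at -1.83 ± 0.20, and 6 and 3 adjusted over the list alone. Phosphate starvation (adjusted p = 0.936, median 0.04 but mean -0.06) included PHT1;4 at -1.09 ± 0.13, with 2 higher and 3 lower genes, or 2 and 4 adjusted over the list alone. Sulfur limitation (adjusted p = 0.143) had 3 higher and 1 lower by either adjustment, the lower one being SULTR1;2 (-1.28 and -2.41 on the 2 arrays). The hypoxia list (adjusted p = 0.262) had 3 higher, such as SUS1 (1.26 ± 0.24), and 2 lower by either adjustment. The heat shock list (adjusted p = 0.992) had 1 higher and 2 lower, DREB2A being at -0.74 ± 0.038, by either adjustment. In the DNA damage list (adjusted p = 0.262) TSO2 had -0.40 ± 0.025 and passed over all genes, with 0 adjusted over the list alone. Of the 10 reference genes (adjusted p = 0.226), 9 did not pass by either adjustment. UBQ10 passed by both, but no change is read from it, since its spot was saturated in both channels on replicate 1 and in the aluminium channel on replicate 2.

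**Figure D3:**
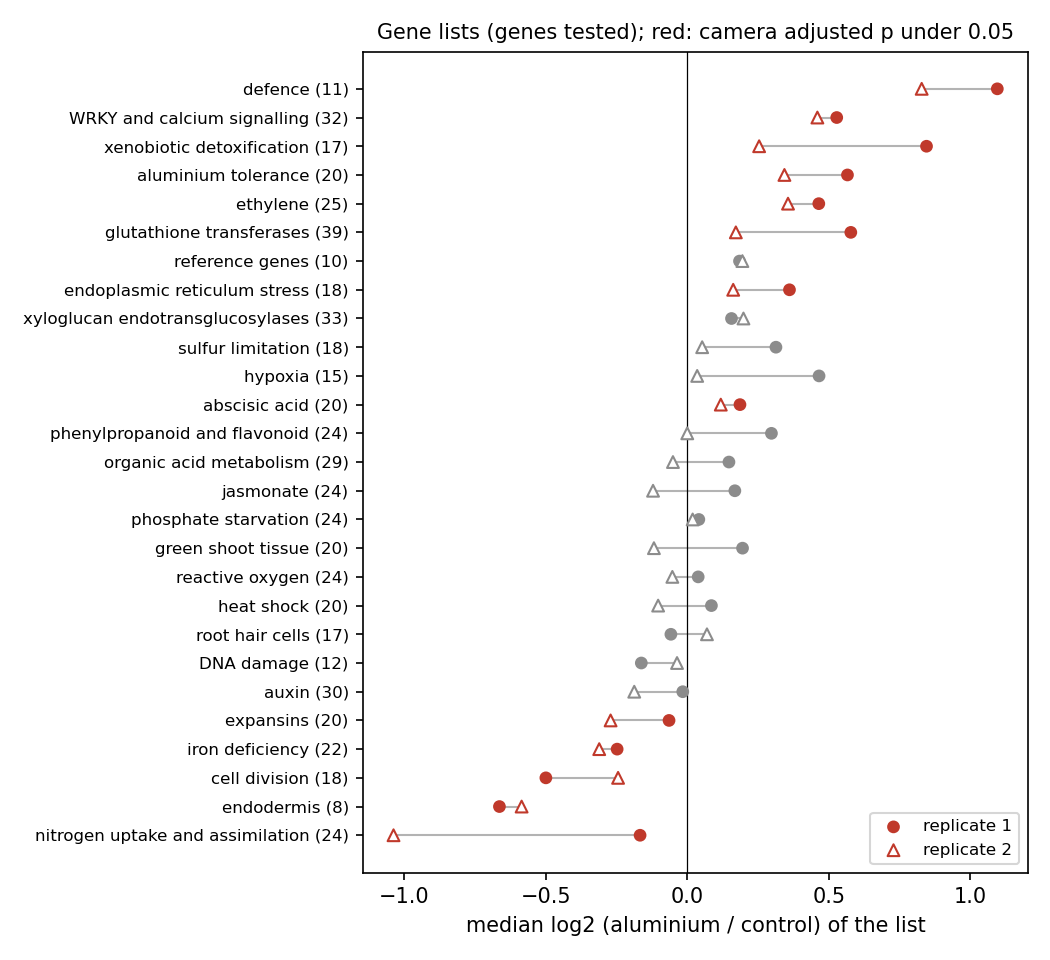
Median log2 ratio of aluminium over control for each of the 27 tested gene lists, with the number of genes tested in brackets, circles for replicate 1 and open triangles for replicate 2, red where camera's adjusted p was under 0.05. The defence list lies highest, and the nitrogen list has the widest gap between the arrays, -0.17 against -1.04.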

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

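In the tests here, that of dye bias for the endodermal genes was chosen after the result was seen. Probes without a gene name shared by both array layouts were not used in the comparison, and 6 of these 1047 probes were at least 2-fold higher in the aluminium RNA on both arrays, 2 at least 2-fold lower and 0 of opposite sign. The highest had mean log2 ratios of 2.13 ± 0.43 and 2.07 ± 0.29 (SD, n = 2).

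Among endodermal genes ESB1, PER64 and CASP1 fell, while SCR, MYB36, SGN3 and CASP5 did not pass. Dye bias could not be tested with CASP1, ESB1 and PER64, whose 6 ratios over both dye orientations were all at or below -1.68. ESB1 and PER64 were named for a large change shared by both arrays, and CASP1 for a small p from the same ratios. Genes so chosen could hardly show the opposite signs that a dye effect leaves. The endodermis list, fixed before the data were examined, had medians of -0.66 and -0.59 in the opposite dye orientations. A dye effect alone would turn the sign, so these medians argue against it for the list median only. A loss of endodermal cells that lowers all their markers alike is argued against by the identity gene SCR. It lay 1.47 above the median of the 5 measured barrier genes. The SE of 0.15 is that of SCR and CASP1, the gene at the median, and leaves out the spread among the 5 genes. CASP5, itself a barrier gene, lay above SCR. SCR alone cannot tell whether only some endodermal cells were lost, so a change in cell makeup stays open. A lower level of the regulator MYB36 stays open, because its mean of -0.23 ± 0.11 (SE) met neither bound set beforehand. An effect of the aluminium treatment stays open, and how it would act on these genes was not tested.

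Nitrogen genes were lower on replicate 2 than on replicate 1 in 22 of 24 cases, with a gap between list medians of 0.87. The gap was 0.91 with the scanner software's ratios and 0.86 without background correction, but 0.20 with median centring, where 13 of 24 were lower on replicate 2. By the bound set beforehand, this small gap is what a contribution of the loess normalization would give, so the normalization may account for much of it. Median centring leaves any dye trend with signal uncorrected, so the reason for the smaller gap was not tested. Dye and replicate cannot be told apart here, since each orientation has 1 array, and no biological explanation of a difference between replicates was tested.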

How the results depend on the processing

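None of the called named genes or lists changed direction under the alternatives run, but the number of gene calls varied widely. The called named genes had the same sign on both arrays, so either replicate alone could not turn them. Other scalings of the same arrays hardly could, so the kept direction of these genes is weak support. The higher and lower calls were 170 and 118 with the scanner software's ratios (166 and 117 of them also called in the main setting), 889 and 586 with median centring (prior degrees of freedom then infinite), 2382 and 2054 at adjusted p under 0.10, and 0 and 0 with the series matrix values, where limma had 5073 genes at an unadjusted p under 0.05, and 0 and 0 with the unmoderated one-sample test, which had 2161 and a smallest adjusted p of 0.201. The other settings stayed within 1.5 times the main counts. Genes 2-fold lower on both arrays numbered 269 with the scanner software's ratios and 297 with the series matrix values, and those of opposite sign 23 and 30, against 2 with offset 16 and 2 with median centring. On single arrays, a value with no test, 372 to 616 genes were at least 2-fold higher and 297 to 308 lower. The correlation of the arrays was 0.77 with offset 16, 0.68 with the scanner software's ratios, 0.67 with the series matrix values and 0.52 with median centring. The cause was not tested. Of the lists, 0 were called by camera with an estimated correlation, with 0 at an unadjusted p under 0.05, and 0 by fry, which had 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.184. Of the named genes, 68 lost their call with the scanner software's ratios, 113 with the series matrix values and 23 with median centring. Ratios over 1.5 times as far from 0 were found for 8 of the 115 called named genes with the scanner software's ratios and 15 with the series matrix values, and 0 were as much nearer. Of those in the text, the series matrix gave GLP6 5.16, BHLH38 -3.16, BIP3 2.60, WRKY75 2.01, CYP81D8 1.95, PHT1;4 -1.64, LEA7 1.59, GH3.2 1.405, RAH1 0.87, CYCB1;1 -0.83 and PLT1 -0.82. Naming all probes by either layout, chosen after seeing the data, gave 1580 higher and 1219 lower genes. Averaging probes changed nothing, since each gene had 1, and Aquantile scaling leaves the ratios as they are. A signal 4.60 to 8.62 times the background limits dim genes, and 2 arrays limit the rest. No paired analysis was possible beyond the main test because that test, on the ratio within each array, is already paired.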

Other observations

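Among 253 families of at least 10 genes, formed from the probe descriptions after the data had been seen, camera called 9 higher and 11 lower, and none with an estimated correlation (smallest adjusted p = 0.992). Of 118 genes described as 60S ribosomal proteins 26 fell and 0 rose (family median -0.29, adjusted p = 1.07e-12), and of 91 for the 40S subunit 11 fell and 0 rose (-0.26, adjusted p = 9.60e-11). Chaperonin genes (-0.37 on replicate 1 and -0.16 on replicate 2), histone H2A genes (-0.26) and leucine-rich repeat transmembrane kinase genes (-0.17) also had lower medians. None of these medians changed sign over the 5 other scalings. Disease resistance protein genes had 27 of 150 higher and 3 lower (median 0.13). The family of NAC factors, listed as no apical meristem, had 21 of 81 higher and 0 lower (median 0.08). Separately described disease resistance families were not called, one with 3 of 25 higher and 0 lower (adjusted p = 0.174) and one with 0 of 11 higher and 1 lower (adjusted p = 0.893). Nor was the Toll-Interleukin-Resistance family (adjusted p = 0.548).

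Several of the largest changes belonged to genes without a symbol, chosen after their values were seen. AT3G47480, described as a calcium-binding EF hand family protein, had 4.41 ± 0.98, and AT1G20380, described as a prolyl oligopeptidase, -3.67 ± 0.48. AT4G13580 (-3.46) and AT3G24020 (-3.26) carry the same description as ESB1, disease resistance-responsive family protein. That family, ESB1 included, had 5 of 14 lower and 0 higher (adjusted p = 0.0490, and adjusted p = 0.992 with an estimated correlation), a count that includes the genes singled out. AT3G55230 (-3.24) and AT2G39430 (-2.70) carry related descriptions and were not counted in it. Among the higher genes were a calcium-transporting ATPase, AT3G22910 (4.03), and the AAA-type ATPase genes AT5G17760 (3.41), AT3G28510 (2.91) and AT1G43910 (2.97). The AAA-type ATPase family as such was not called, with 8 of 35 higher, 3 lower and a median of 0.03 (adjusted p = 0.495).

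Among families of membrane traffic, grouped here after their values were seen, camera called higher those of SNF7 proteins (7 of 13 higher, median 0.47), ADP-ribosylation factors (5 of 16, 0.42 and 0.21 on replicates 1 and 2) and Ras-related GTP-binding proteins (6 of 34, 0.16), with 0 lower in these 3 and an adjusted p = 0.992 for each with an estimated correlation. A separately described Ras-related GTP-binding family had 4 of 12 higher and 1 lower (adjusted p = 0.282) and was not called. Nor were the exocyst EXO70 family, with 2 of 14 higher and 1 lower (adjusted p = 0.736), the endomembrane protein family, with 0 of 11 past the threshold (adjusted p = 0.992), and the emp24 (adjusted p = 0.257), prenylated rab acceptor (adjusted p = 0.261) and epsin (adjusted p = 0.604) families. Camera did not call the RabGAP (adjusted p = 0.945) and reticulon (adjusted p = 0.350) families either. The same held for the SEC14 cytosolic factors (adjusted p = 0.432) and a separately described SEC14 cytosolic factor family (adjusted p = 0.836). This grouping followed no fixed list.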
